A study of Caenorhabditis elegans with 6 samples.

How the data were processed

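Total RNA of 6 samples of mixed-stage worms, 3 flight and 3 ground, had been amplified and labelled with Cy3 from 0.5 µg of RNA per sample and hybridised to Agilent one-colour C. elegans arrays with 60-base probes, per the labels' protocols. The 6 deposited scanner files hold spot intensity values made with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. Per the file headers, the processed intensity of a spot was background-subtracted and detrended within its array by that software, with low signals replaced by surrogate values. The files also hold the raw mean and local background intensity and flags for each spot, which per the file headers come from the same software. A deposited value table of 34283 probes is on the log2 scale. Its scale and centring were not stated and were found from the values. Each column lay on a line of slope 1 (0.9997 to 1.0001) against log2 of the processed signal minus the array's 75th percentile minus the median of the 3 ground arrays (r from 0.9997 to 1.0000 across probes, which are not independent). The median of the 3 ground columns was 0 in each row. The column medians were 0.00 for the ground arrays and -0.02, 0.00 and -0.06 for flight replicates 1 to 3. Neither scale nor centring stayed unknown. The direction follows from the columns as titled, and the sample descriptions contradict those titles, as described below.

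The main values were log2 of the processed signal minus the same array's 75th percentile. The 75th percentile of the signal lay between 1595 and 2101. Control spots were left out, spots marked as outliers by the scanner software (9 to 21 per array) were treated as missing, and spots of one probe were averaged. No gene spot was saturated. Of 43603 distinct probes, 36290 were matched by systematic name, symbol or accession to a gene of the reference table (assembly WBcel235), 34733 of them to a single gene and 1557 to several, and 7313 were left unnamed. Probe coordinates are those of the files (ce4), and the reference table was used only for names and for which genes neighbour each other. A probe entered the test when it was well above background on all 3 arrays of at least one group. Each gene was represented by its probe with the highest mean over the 6 arrays, which left 15745 genes, 735 of them on a probe that matches several genes. Of 2695 changed genes with several tested probes, 2390 had differences of the same sign on all of these probes, whether or not each probe passed. Where a probe was not well above background on any array of one group, its fold is given as a bound. The bright group's mean was set against the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

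Flight was compared with ground with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block, Benjamini-Hochberg adjustment over all genes tested). A gene counted as changed at an adjusted p under 0.05, and as changed at least 2-fold when the log2 difference was also at least 1 in size. A set of 38 gene lists, chosen from general knowledge of the worm's tissues, stages and stress responses before the data were examined, was tested with camera at its preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were run beside it. Some genes belong to more than one list. The genes named were chosen by a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among genes with a symbol, an adjusted p under 0.05 and no overlap between groups (at most 3 per symbol stem), up to 4 members of each list with the smallest adjusted p (filled up to 2), and hlh-1, unc-54, myo-1, myo-2 and myo-3 from earlier work on flown worms.

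Replicate numbers in the labels are shared by both groups and follow the position on the slide. It was checked whether arrays with the same number deviate together. Across genes, the deviations from the group means correlated at 0.12, 0.18 and 0.28 for replicates 1, 2 and 3, each above the threshold of 0.1 set for pairing. Arrays with different numbers correlated at -0.22 to 0.087, the highest being ground replicate 2 with flight replicate 1. The numbers were treated as possible pairs. The pairing rests on this correlation and the shared slide position, not on a statement in the labels. A fit with the replicate number as a block was therefore made beside the main one.

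The test was tried on simulated data with the means and residual SDs of the 15745 genes and 200 genes changed. For the comparison of flight with ground it recovered 53.7% of genes changed 1.25-fold, 76.1% of those changed 1.5-fold and 95.5% of those changed 2-fold, with 3 false calls. In the real data 60.2% of the genes passed, far more than were changed in the simulation, so these rates need not hold there. A list shifted by 0.2 on the log2 scale in independent simulated genes was called by camera, and no other list was. That says nothing about camera on genes that vary together.

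The alternatives tried were quantile normalization, the array median or the E1A spike-in probes (7 of 10 used) in place of the 75th percentile, normexp background correction with an offset of 50, no filter on dim probes, a filter requiring all 6 arrays, and the mean of all probes of a gene. Further ones were the deposited value table, an intensity trend in the variance, outlier spots kept, the replicate block, and each array left out in turn. Leaving out replicate 3 of both groups was added after seeing the data. Figures were drawn with matplotlib 3.10.9.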

Results

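Gene expression was measured in wild-type Caenorhabditis elegans (strain N2) of mixed stages that had been kept on the International Space Station, and in ground controls. About 10000 worms were grown in CeMM, a chemically defined liquid medium without bacteria. Transport to the station took 2 days at 12 °C, culture on the station lasted 8 days at 18 °C, and recovery took 1 day at 18 °C before freezing, so that the flown worms spent 10 days in microgravity. The same protocol text is attached to the ground samples, whose own temperatures and times are not stated. The design implies one comparison, 3 flight samples against 3 ground samples, and it asks which transcripts differed in abundance after that exposure. The flown worms were frozen after the recovery day, so "in flight" below means in the flight samples and not on the station. Effects of the flight and of the recovery cannot be told apart. Each sample was labelled with Cy3 and hybridised to its own Agilent one-colour array with 43803 gene spots. Between 69.8% and 74.1% of the spots on an array were well above background, and no gene spot was saturated. The number of arrays limits the precision of every value given here.

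The samples were taken as ground or flight from their titles and source names. A free-text description attached to each of the 6 samples says the opposite, calling the ground samples flight and the flight samples ground. If those descriptions were right, every direction given here would turn. The deposited value table was centred on the median of the arrays titled ground, which served there as the baseline. All ground samples lay on one slide and all flight samples on the other, so slide and group cannot be told apart. The labels do not say that the replicates came from separate cultures, and the p-values then measure only the spread between these samples, which may be technical. The median SD between arrays of one group was 0.066 on the log2 scale over all genes. For 21 probes with 5 spots each, the median SD between spots of one array was 0.0743, and that of the probes' 5-spot means between arrays of a group was 0.0747. Means of 5 spots vary less than single spots when spot noise is the only source. For these probes the arrays of a group therefore differed by more than spot noise, and the source of that spread is not known. The first principal component held 74.9% of the variance and separated the groups. The second held 9.27% and set replicate 3 of both groups apart from the other 4 arrays.

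The C-type lectin genes clec-127, clec-128 and clec-132 were among the genes that rose most in flight, and the muscle myosin genes of the pharynx were among those that fell to less than 50% of the ground level. Of 15745 genes tested, 9477 (60.2%) differed between flight and ground with limma at a Benjamini-Hochberg adjusted p under 0.05, of which 4587 were higher and 4890 lower in flight. Most differences were small. The median size among the changed genes was 0.31 on the log2 scale, 1357 genes changed at least 1.5-fold, and 228 changed at least 2-fold, 61 of them higher and 167 lower. These counts use the fitted differences, also for genes whose fold is known only as a bound. Of the 228, 193 were also called when all 6 arrays had to be well above background. In 10583 genes (67.2%) the 3 flight arrays all lay on one side of the 3 ground arrays, where chance gives 10%. The split between higher and lower genes depended on the scaling. With the 75th percentile as reference 48.4% of the changed genes were higher in flight, against 56.1% after quantile normalization, 73.3% with the array median and 75.3% with the spike-in probes as reference. The array median and the spike-in reference placed the median of all genes at 0.18 and 0.21 on the log2 scale, against 0.01 with the 75th percentile, and differences are to be read relative to these shifts.

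Among the genes higher in flight, scl-27 (ZK6.3, probe on chromosome V at 401530-401589 of ce4), which encodes a protein of the SCP/TAPS family, was 5.98-fold higher (log2 difference 2.58 ± 0.07, SE, n = 3 arrays per group, limma adjusted p = 5.5e-06). Its scaled log2 signal was -3.73 ± 0.11 (SD, n = 3) on the ground arrays and -1.15 ± 0.07 (SD, n = 3) on the flight arrays. The C-type lectin genes clec-127, clec-128 and clec-132 (W10G11.5, W10G11.6 and W10G11.13) have probes on chromosome II between 3568137 and 3578088 of ce4. They were 5.75-fold, 5.94-fold and 5.24-fold higher (limma adjusted p from 7.51e-06 to 4.11e-05). Only 2 of the 3 ground arrays measured clec-127 well above background. Further genes picked by the rule for naming genes, which takes at most 3 per symbol stem, were bath-25 (3.76-fold), the transthyretin-related gene ttr-42 (3.57-fold) and the neuropeptide gene nlp-39 (3.42-fold). The chemoreceptor gene srtx-1 (2.86-fold), pals-9 (2.53-fold) and scl-20 (2.34-fold) followed. On the ground arrays lys-9, a lysozyme gene, and srh-131, a chemoreceptor gene, were not well above background. They were at least 1.41-fold and at least 1.69-fold higher in flight (limma adjusted p = 7.64e-05 and 0.0149), and leaving out replicate 3 of both groups ended the call of srh-131 (limma adjusted p = 0.0509).

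Among the genes lower in flight, oac-20, which encodes an acyltransferase-like protein, was not well above background on any flight array. It was at least 3.85-fold lower there (limma adjusted p = 4.12e-06). The nuclear receptor gene nhr-260 fell by 1.70 ± 0.04 on the log2 scale (SE, n = 3 arrays per group), the lipase-related gene lips-13 fell by 1.55 ± 0.05 and idpp-1 fell by 1.52 ± 0.05 (limma adjusted p from 4.65e-06 to 1.09e-05). The log2 difference was -1.88 for txt-12, -1.84 for oac-6, -1.79 for pugs-11 and -1.59 for pyt-1. It was -1.96 ± 0.34 for fipr-12, -1.95 ± 0.42 for dmd-8 and -1.63 ± 0.39 for sri-24 (SE, n = 3 arrays per group), whose ground arrays had SDs between 0.60 and 0.86. The value of oac-6 rests on 2 flight arrays, as its spot on the remaining one was marked as an outlier. With outlier spots kept its difference was -0.89 ± 0.73 (SE, n = 3 arrays per group; limma adjusted p = 0.324), and the deposited value table gave -0.90 ± 0.73.

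**Figure D1:**
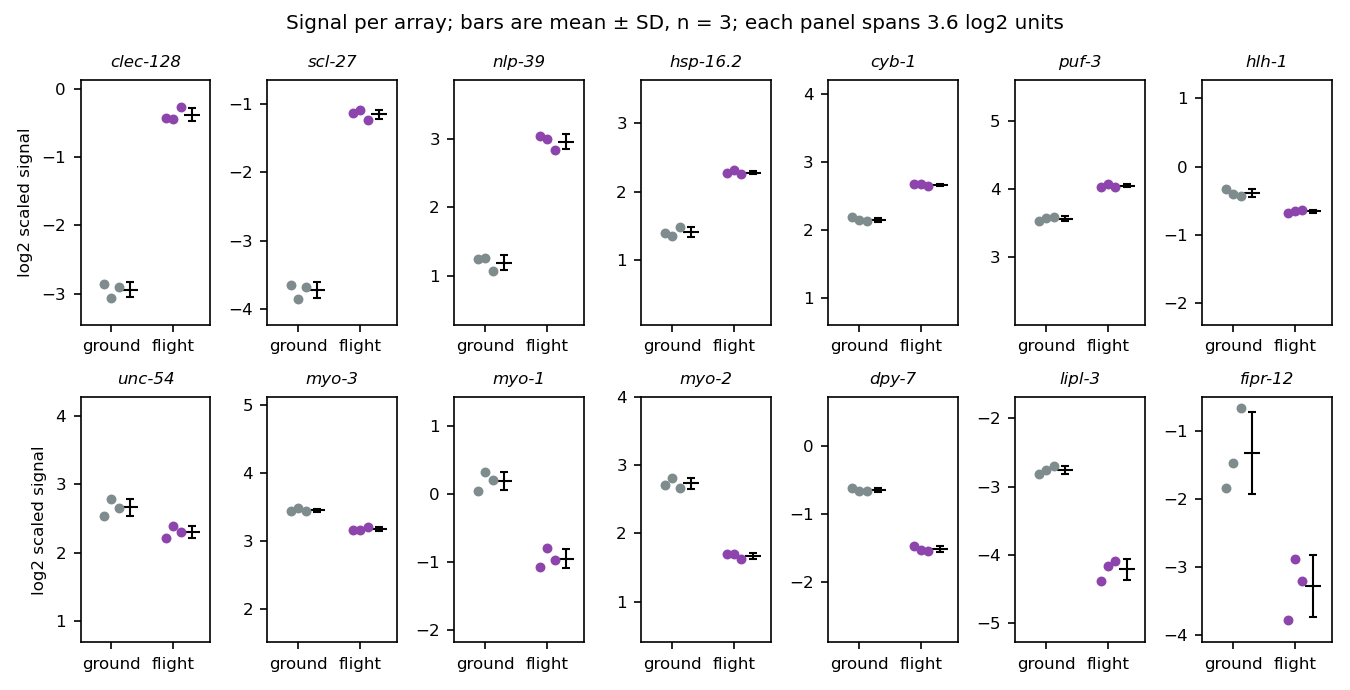
Signal of 14 genes on each array, as log2 of the scanner's processed signal relative to the array's 75th percentile (vertical axis), for the 3 ground arrays (grey) and the 3 flight arrays (purple), with mean ± SD (n = 3) as black bars. In the 14 panels the flight arrays lie apart from the ground arrays, with differences of the smallest size for hlh-1 (-0.27) and of the largest for scl-27 (2.58) and clec-128 (2.57); with the array median or the spike-in probes as reference hlh-1, unc-54 and myo-3 no longer pass the test.

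Muscle genes were lower in flight, both those of the pharynx, the feeding organ, and those of the body wall. All 9 pharyngeal muscle genes fell (median log2 difference -0.85, camera adjusted p = 4.5e-05, adjusted p = 0.0906 with an estimated correlation). The pharyngeal myosin heavy chain genes myo-1 and myo-2 fell by 1.14 ± 0.09 and 1.06 ± 0.05 on the log2 scale (SE, n = 3 arrays per group; limma adjusted p = 0.000149 and 2.56e-05). The troponin T gene tnt-4 fell by 0.89, the troponin C gene tnc-2 fell by 0.85 and ceh-22, which encodes a homeodomain factor of pharyngeal muscle, fell by 0.83. Of the 38 genes for body wall muscle sarcomeres and attachment, 28 fell, 1 rose and 9 did not pass (median log2 difference -0.30, camera adjusted p = 7.36e-06, adjusted p = 0.0867 with an estimated correlation). Examples are unc-89, which encodes the giant M-line protein obscurin (-0.69), and the troponin I gene tni-3 (-0.64). With the array median as reference 18 of these genes fell, and with the spike-in probes 3. The body wall myosin genes unc-54 (-0.36 ± 0.08) and myo-3 (-0.28 ± 0.04) and the myogenic factor gene hlh-1 (-0.27 ± 0.04; SE, n = 3 arrays per group) were lower with the 75th percentile as reference (limma adjusted p from 0.000858 to 0.00601). None of these genes passed with the array median (limma adjusted p from 0.0513 to 0.0627) or the spike-in probes (0.426 to 0.753) as reference. Of the 4 myogenic transcription factor genes, hlh-1 and unc-120 passed, and unc-120 did not pass with the spike-in probes (limma adjusted p = 0.372). The list did not shift (median -0.11, mean 0.06, camera adjusted p = 0.493), and its counts were 1 up and 1 down with the array median and 1 up and none down with the spike-in probes. Genes of intermediate filaments (7 of 12 fell, none rose; camera adjusted p = 0.0141, adjusted p = 0.127 with an estimated correlation), led by ifc-1 (-0.92), and of the basement membrane (9 of 15 fell, none rose; camera adjusted p = 0.002, adjusted p = 0.0967 with an estimated correlation), with lam-3 (-0.67) and gpn-1 (-0.63), were lower as lists. Intermediate filaments lost their call with the array median or the spike-in probes as reference (camera adjusted p = 0.0554 and 0.0788), and the basement membrane list lost its call with the spike-in probes (0.0661), where its median turned from -0.19 to 0.007. Of the intermediate filament genes 3 rose and 3 fell with the array median and 2 fell with the spike-in probes, and of the basement membrane genes 3 and 2 fell. Adjusted over the list alone, the counts were the same except that 8 intermediate filament genes fell. Of the 15 tubulin genes, 3 rose and 6 fell, and 4 rose and 6 fell adjusted over the list alone. That list did not shift (camera adjusted p = 0.493), and its balance turned with the array median (6 up and 2 down) and the spike-in probes (2 up and none down).

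Neuronal and signalling genes were also lower. Of the 69 neuropeptide genes 57 fell and 2 rose (median log2 difference -0.39, camera adjusted p = 2.69e-10, adjusted p = 0.0906 with an estimated correlation). The largest falls included those of nlp-30 (-1.52), nlp-26 (-1.47) and nlp-31 (-1.25), of which nlp-30 and nlp-31 are known as antimicrobial peptide genes of the epidermis rather than as neurotransmitters. Against the direction of the list, nlp-39 rose. Of 31 genes for dopamine, serotonin, GABA and glutamate signalling, 27 fell and 2 rose (median -0.51, camera adjusted p = 2.83e-07, adjusted p = 0.0694 with an estimated correlation). They included avr-15, which encodes a glutamate-gated chloride channel of the pharynx (-0.92), and the dopamine transporter gene dat-1 (-0.77). Acetylcholine signalling genes fell in 15 of 18 cases and rose in 1 (median -0.46, camera adjusted p = 0.000226, adjusted p = 0.127 with an estimated correlation), with the muscarinic receptor gene gar-3 (-0.80) and eat-2, which encodes a nicotinic receptor subunit of the pharynx (-0.76). Synaptic and pan-neuronal genes fell in 20 of 26 cases and rose in 2 (median -0.29, camera adjusted p = 0.000242, adjusted p = 0.0867 with an estimated correlation). Their members with the smallest adjusted p, the synaptotagmin gene snt-1 (-0.44) and the complexin gene cpx-1 (-0.56), did not pass with the spike-in reference (limma adjusted p = 0.237 and 0.0718). Of the 34 insulin-like peptide genes, 21 fell and 2 rose (median -0.27, camera adjusted p = 0.00177, adjusted p = 0.494 with an estimated correlation), with ins-15 (-1.38), ins-35 (-1.04) and ins-16 (-0.99). TGF-beta signalling genes fell in 11 of 17 cases and rose in 1 (camera adjusted p = 0.019, adjusted p = 0.127 with an estimated correlation), with lon-1 (-0.69). The call of the TGF-beta list was lost with the spike-in reference (camera adjusted p = 0.161). Under array-median scaling 40 neuropeptide genes fell and 7 rose, 23 dopamine, serotonin, GABA and glutamate genes fell and 2 rose, and 12 acetylcholine genes fell and 2 rose. Under the same scaling 10 synaptic genes fell and 3 rose, 14 insulin-like genes fell and 7 rose, and 5 TGF-beta genes fell and 4 rose. The spike-in probes gave, in the same order, 11, 9, 5, 1, 6 and 1 genes that fell and 1, 2, 1, 1, 4 and 1 that rose. Adjusted over the list alone, 28 genes for dopamine, serotonin, GABA and glutamate signalling fell, and the other counts were the same. The insulin signalling and DAF-16 target list went both ways, with 8 genes up and 6 down of 22 (8 and 7 adjusted over the list alone). Its counts were 7 up and 9 down with quantile normalization, 12 up and 6 down with the array median and 5 up and 2 down with the spike-in probes. It did not shift (camera adjusted p = 0.98), and its median of 0.08 and its mean of -0.04 differed in sign, as did camera and fry.

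Cuticle genes fell in a similar way. Of 40 genes for the larval cuticle and moulting, 32 fell and 2 rose (median log2 difference -0.50, camera adjusted p = 1.05e-08, adjusted p = 0.0519 with an estimated correlation). Among them were the cuticle collagen genes dpy-7 (-0.86), dpy-8 (-0.82) and dpy-9 (-0.70) and mlt-7, which encodes a peroxidase needed for moulting (-0.89). Of 11 adult cuticle collagen genes, 9 fell and none rose (median -0.54, camera adjusted p = 0.000242, adjusted p = 0.184 with an estimated correlation), with bli-2 (-1.18) and bli-1 (-0.90). With the array median 27 larval cuticle and 7 adult collagen genes fell, and with the spike-in probes 16 and 4. Both counts were the same adjusted over the list alone.

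Genes of the germline, of DNA replication and cell division, and of DNA damage and apoptosis were higher in flight, by less than 1.5-fold in nearly every case. Of the 27 oocyte and eggshell genes 26 rose and none fell (median log2 difference 0.41, camera adjusted p = 2.24e-08, adjusted p = 0.15 with an estimated correlation). They included nos-2, a nanos-related gene whose maternal RNA is translated in germline precursors (1.4-fold), the PUF-family RNA-binding protein genes puf-3 (1.4-fold) and puf-5 (1.35-fold), and the eggshell chitin synthase gene chs-1 (1.31-fold). Germ granule and meiosis genes rose in 29 of 33 cases and fell in 1 (median 0.33, camera adjusted p = 7.12e-08, adjusted p = 0.0519 with an estimated correlation), with the Argonaute gene wago-1 (0.40) and the meiotic axis gene htp-3 (0.35). Of the 32 DNA replication and cell division genes 30 rose and none fell (median 0.33, camera adjusted p = 5.99e-09, adjusted p = 0.0694 with an estimated correlation), with the cyclin B gene cyb-1 (0.51), the centromeric histone gene hcp-3 (0.43) and the Aurora kinase gene air-1 (0.40). DNA damage and apoptosis genes rose in 26 of 34 cases and fell in 1 (median 0.27, camera adjusted p = 4.1e-06, adjusted p = 0.0967 with an estimated correlation). The caspase gene ced-3 (0.55), rad-54.L (0.39) and brc-1 (0.34), the latter pair acting in DNA repair by recombination, were among those that rose, while phg-1 fell by 0.66. Of 45 sperm genes 17 rose and none fell (median 0.13, camera adjusted p = 0.00177, adjusted p = 0.605 with an estimated correlation). In the vitellogenin list vit-1 passed (0.64 ± 0.05, SE, n = 3 arrays per group), and the list did not shift (camera adjusted p = 0.587). The gene vit-6 (limma adjusted p = 0.0838) passed when the replicate number was used as a block (limma adjusted p = 0.0112), and 4 of the 6 vitellogenin genes rose with the array median. Of the 12 early zygotic genes 4 rose and 2 fell, without a shift of the list (camera adjusted p = 0.493). Of the sperm genes, 41 rose with the array median and 11 with the spike-in probes. Adjusted over the list alone, 27 DNA damage genes and 15 sperm genes rose, 4 early zygotic genes rose and 1 fell, and the other counts were the same.

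**Figure D2:**
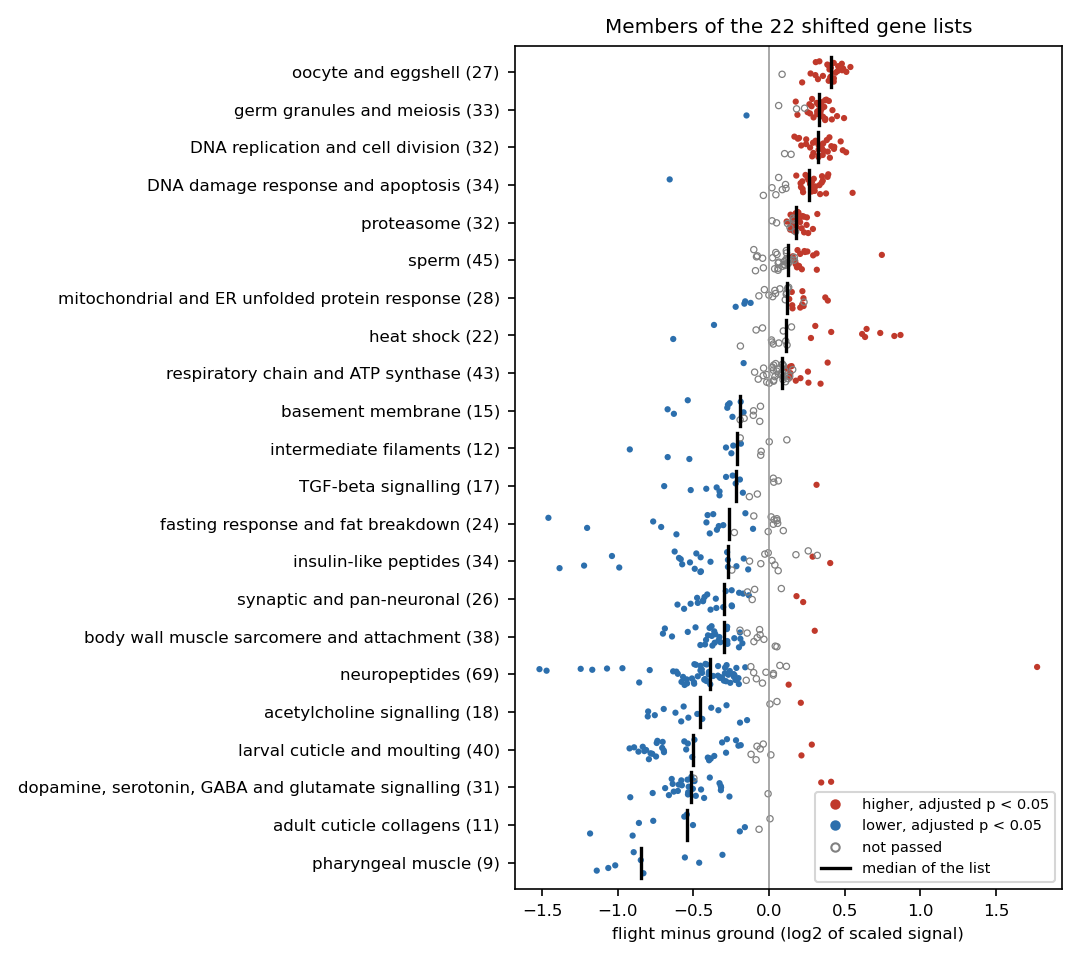
Log2 difference between flight and ground (horizontal axis) of each member of the 22 lists that shifted, one point per gene, with the number of tested genes in parentheses. Red and blue points passed the test (n = 3 arrays per group), open points did not, and black bars mark each list's median, from -0.85 for pharyngeal muscle to 0.41 for oocyte and eggshell genes; with the spike-in probes as reference the median of the basement membrane list turned to 0.007, and the medians of the other 21 lists kept their sign under each scaling tried.

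Protein quality control genes were higher as lists. Proteasome genes rose in 25 of 32 cases and none fell (median 0.18, camera adjusted p = 7.93e-06, adjusted p = 0.127 with an estimated correlation), with rpt-3 (0.32) and pas-7 (0.29). Of 22 heat shock genes 9 rose and 2 fell (camera adjusted p = 0.0246, adjusted p = 0.216 with an estimated correlation). The small heat shock protein genes hsp-16.2 and hsp-12.6 were 1.83-fold and 1.55-fold higher and the inducible chaperone gene hsp-70 was 1.56-fold higher, whereas hsp-12.2 fell by 0.63 on the log2 scale. Of 28 genes of the mitochondrial and endoplasmic reticulum unfolded protein responses 11 rose and 4 fell (camera adjusted p = 0.0394, adjusted p = 0.148 with an estimated correlation), with the chaperone genes enpl-1 (0.39) and hsp-4 (0.37), both of the endoplasmic reticulum. The heat shock list lost its call with quantile normalization and the array median (camera adjusted p = 0.121 and 0.0554), and the unfolded protein response list lost it with quantile normalization and the spike-in reference (0.435 and 0.0949) and without ground replicate 2 (0.0504) or flight replicate 3 (0.0545). With the array median 32 proteasome, 15 heat shock and 23 unfolded protein response genes rose, and with the spike-in probes 11, 9 and 8. The counts were the same adjusted over the list alone, except that 27 proteasome genes rose. Autophagy genes (4 up and 6 down of 27, or 3 and 5 adjusted over the list alone; camera adjusted p = 0.794) and cytosolic ribosomal protein genes (2 up and none down of 79, none adjusted over the list alone; camera adjusted p = 0.819) did not shift. With the array median 15 autophagy genes rose and 3 fell, and 29 ribosomal protein genes rose. The ribosome list was called when flight replicate 3 was left out (camera adjusted p = 0.0168).

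Genes for fasting and fat breakdown fell in 14 of 24 cases and none rose (median -0.27, camera adjusted p = 0.00235; adjusted p = 0.0967 with an estimated correlation). These counts were 8 up and 12 down with the array median, and with the spike-in probes 5 fell. The lysosomal lipase gene lipl-3 fell by 1.46 on the log2 scale, the carnitine palmitoyltransferase genes cpt-3 and cpt-4 were 2.3-fold and 1.64-fold lower, and the glyoxylate cycle gene icl-1 fell by 0.77 on the log2 scale, although the differences of the 8 probes of icl-1 did not all share a sign. Respiratory chain and ATP synthase genes rose in 11 of 43 cases and fell in 1 (median 0.09, camera adjusted p = 0.0128, adjusted p = 0.165 with an estimated correlation), with ucr-2.3 (0.39) and asb-1 (0.34). That call was lost with quantile normalization and the spike-in reference (camera adjusted p = 0.377 and 0.0721), and 38 genes rose with the array median but 5 with the spike-in probes. The remaining metabolic lists did not shift. These were fatty acid synthesis and desaturation (2 up and 10 down of 20, camera adjusted p = 0.118), pyruvate dehydrogenase and the TCA cycle (6 up and 3 down of 27, camera adjusted p = 0.301) and glycolysis and gluconeogenesis (3 up and 5 down of 21, camera adjusted p = 0.861). Quantile normalization alone called the fatty acid list (camera adjusted p = 0.0105). The balance of the fatty acid and glycolysis lists turned with the array median, where 9 fatty acid genes rose and 2 fell and 9 glycolysis genes rose and 1 fell, while 16 TCA cycle genes rose and none fell. Quantile normalization gave 6 TCA cycle genes up and 7 down. Adjusted over the list alone, 6 respiratory chain genes rose and none fell, 6 TCA cycle genes rose and 2 fell, 1 glycolysis gene rose and 2 fell, and the other counts were the same.

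The remaining stress lists and the intestine list did not shift. Of 44 innate immunity genes 11 rose and 17 fell (camera adjusted p = 0.436), with the saposin-like gene spp-9 2.09-fold higher on a probe shared by 2 genes and clec-67 2.03-fold lower. Hypoxia response genes rose in 6 and fell in 3 of 14 cases (camera adjusted p = 0.864), and sqrd-1, which encodes a sulfide oxidoreductase, was 2.18-fold higher. Of 25 intestine genes 5 rose and 9 fell (camera adjusted p = 0.354), with the cysteine protease genes cpr-4 (-1.17) and cpr-1 (-0.84) lower. Quantile normalization called the intestine list (3 up and 13 down, camera adjusted p = 0.0207), while 12 of its genes rose and 5 fell with the array median. Oxidative stress defence (14 up and 6 down of 32, camera adjusted p = 0.144), cytochrome P450 and UGT (15 up and 21 down of 50, camera adjusted p = 0.864) and metal response genes (5 up and 7 down of 20, camera adjusted p = 0.587) likewise went both ways. Array-median scaling turned the balance to 27 up and 10 down for P450 and UGT, 10 up and 6 down for metal response and 17 up and 12 down for innate immunity genes, and gave 25 up and 4 down for oxidative stress and 8 up and 2 down for hypoxia genes. Without the filter on dim probes the oxidative stress list was called (camera adjusted p = 0.0367). In the oxidative stress list gpx-3 fell by 0.61, in the P450 and UGT list ugt-8 fell by 0.97, and in the metal response list cdr-3 rose by 0.53. The counts were the same adjusted over the list alone, except that 18 innate immunity genes fell.

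Of the 38 lists, 22 shifted relative to all other genes in camera with its preset correlation, 9 up and 13 down. With an estimated correlation camera called 0 of the 38 (14 at an unadjusted p under 0.05), and the smallest adjusted p was 0.0519. That value belonged to the larval cuticle and the germ granule lists. Their estimated correlations, -0.012 and -0.0024, lay below the preset 0.01. A higher correlation between genes therefore does not account for the loss of these calls.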

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

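The test of unnamed probes, and those of adults, somatic tissue and moulting larvae, were chosen after the results were seen. The splits of the arrays, the second probes and the GC content were planned before.

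Probes that could not be matched to a gene entered no comparison of the report, and they were looked at because a signal appeared there above the level of the ground samples. Of 2740 such probes, 156 were higher and 368 lower in flight with limma at an adjusted p under 0.05, with the largest rise 0.85 and the largest fall -1.58 on the log2 scale. All 10 of them that changed at least 2-fold were lower.

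The first pattern is the large number of changed genes. The tables argue against an effect of the slide on single probes as its whole cause. Of 2244 changed genes with a second probe whose coordinates do not overlap the first, 90.6% (95% exact interval 89.3 to 91.8) differed in the same direction on both probes. The interval treats genes measured on the same arrays as independent. A trend with the GC content of the probes is a separate explanation, and the tables argue against it as well: over 4 bins of GC content the median difference stayed between -0.021 and 0.027 on the log2 scale, so there was little trend to remove, and 9238 of the 9477 changed genes still passed in the same direction after its removal. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave 9477 genes and 228 genes changed at least 2-fold, and the highest of the other splits gave 0 and 0 with limma (51 to 443 genes at an unadjusted p under 0.05). Among the splits that part all 3 pairs of same-numbered arrays, the others gave 0 genes as well, and the 6 that part 1 pair, which keep 2 of the pairs together, gave 0 too. Every split but the real one mixes flight and ground arrays on both sides, which widens the spread within each side. These zeros therefore cannot decide the question. A difference in RNA handling, labelling or hybridisation between the 2 slides that acts on whole transcripts stays open and cannot be told apart from the flight itself, as does a swap of the labels of both groups, since each slide held 1 group.

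The second pattern is the rise of germline lists beside the fall of muscle, neuronal and cuticle lists, with 22 of 38 lists shifted in the real split and 18 in the highest of the others (again 1 of 10 splits, too few for a share under 0.05). Every other split keeps 2 arrays of one group together and so holds part of the real difference, and camera with its preset correlation calls lists there without a changed gene. More egg-laying adults in the flight sample as the whole cause would need all their markers to rise by about as much as the oocyte list. The 10 vitellogenin and adult collagen genes had a median log2 difference of -0.035 (95% bootstrap interval -0.33 to 0.073). That lay below the 0.41 of the oocyte list, although vit-1 rose by 0.64. The 6 vitellogenin genes alone had a median of 0.0004, so these markers did not rise with the oocyte list. The set was chosen after the results were seen, and any cause that lowers cuticle genes also lowers its collagens. The bootstrap treats genes measured on the same arrays as independent, so its interval cannot decide the question. An even loss of all somatic tissue would lower pharyngeal muscle and intestine genes alike. Their medians were -0.85 and -0.05, a difference of -0.80 (permutation p = 0.00047, two-sided), so these lists did not fall alike. The pair was chosen after both medians were seen, and pharyngeal muscle has the lowest median of the lists. The permutation also treats genes measured on the same arrays as independent, so its p cannot decide the question. Fewer moulting larvae in the flight sample stays open for the cuticle part. The 180 collagen and hedgehog-related genes outside the fixed lists had a median of -0.51 (95% bootstrap interval -0.55 to -0.44), and 151 of them fell, but any cause that lowers cuticle genes gives this result, and the adult collagen list fell too (median -0.54, against -0.50 for the larval cuticle list). A change of expression within the tissues, by flight, by the recovery day before freezing or by culture conditions, was not separated from a change in the mix of stages.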

How the results depend on the processing

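All values in this part come from alternatives fixed before the data were examined, except the one without replicate 3 of both groups. The count of changed genes lay between 8148 and 11103 in every alternative but one, and the median of all genes moved by more than 0.1 on the log2 scale with the array median and the spike-in probes as reference. With the array median 8143 genes were higher and 2960 lower in flight. With the spike-in probes 4749 genes changed, of which 1171 were lower, and 4431 of the 4749 were also called with the 75th percentile. The named genes that lost their call with the spike-in reference all had the same SE, 0.163. The log2 75th percentile minus the spike-in signal varied from -2.21 to -2.01 among the ground arrays and from -2.16 to -1.77 among the flight arrays. This offset enters every gene of an array alike, so those lost calls share one error and depend on the size of each difference. Normexp background correction left 104 genes changed at least 2-fold, all of them among the 228. The offset of 50 added there shrinks the log2 differences of dim probes. How much of the drop this accounts for was not tested. In other alternatives the 2-fold count lay between 169 (array median) and 333 (no filter, where 20249 genes were tested). Camera with an estimated correlation called 0 lists and fry called 34, and the other alternatives called 17 to 23. One named gene reversed: rps-10 (0.13 on its brightest probe) was -0.54 with the mean of its 2 probes, which disagree. Leaving out each array in turn gave 8148 to 9051 changed genes, 3705 to 4402 higher, 4433 to 4649 lower, 236 to 256 changed at least 2-fold and 21 to 22 lists. Without replicate 3 of both groups there were 8411, 249 and 22, and 7959 of the 8411 genes were among the 9477.

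With the replicate number as a block, 10963 genes changed (5524 higher, 5439 lower), 228 at least 2-fold, and 22 lists shifted. Of the 9477 genes 70 lost their call. Among the genes and lists named, the block changed 1 call, that of vit-6 (adjusted p = 0.0838 without and 0.011 with the block), and no other. Named genes lost their call in 80 of their values under the alternatives, 47 of them with the spike-in probes, and lists in 12. Signal over background limits the dim genes: 84 genes were not well above background on any ground array and 16 on any flight array, and these have only a bound.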

Other observations

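The gene families in this part, the neighbouring genes and their tests were chosen after the results were seen. Genes were grouped by symbol stem, and the 156 families with at least 10 tested genes were compared with all other genes by camera with its preset correlation. In 71 of them the family shifted (28 up, 43 down), and none passed with an estimated correlation (smallest adjusted p = 0.172). Collagen genes (col) fell in 118 of 141 cases and rose in 2 (median log2 difference -0.49, camera adjusted p = 2.25e-17; adjusted p = 0.237 with an estimated correlation), and 12 of them belong to the fixed lists. Globin genes (glb), most of which are expressed in neurons, fell in 29 of 31 cases and none rose (median -0.45, camera adjusted p = 2.74e-08; adjusted p = 0.172 with an estimated correlation). Neuropeptide receptor genes (npr, 32 of 39 fell, median -0.50) and guanylate cyclase genes (gcy, 21 of 27 fell, median -0.60) were lower too, as were the abu genes (11 of 13 fell, median -0.71), at the same estimated-correlation adjusted p of 0.172. The medians of these families kept their sign under each scaling tried, but their size changed. With the spike-in probes they were -0.30 for col, -0.25 for glb, -0.30 for npr, -0.40 for gcy and -0.51 for abu.

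Other families were higher. Nucleoporin genes (npp) rose in 21 of 25 cases and none fell (median 0.23, camera adjusted p = 2.28e-05; adjusted p = 0.172 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 28 of 41 (mrpl, median 0.18) and 19 of 29 (mrps, median 0.21) cases and none fell, with adjusted p = 0.337 and 0.242 with an estimated correlation, while the genes of the cytosolic ribosome did not shift. Skp1-related genes (skr) rose in 14 of 19 cases and none fell (median 0.36, camera adjusted p = 0.000281; adjusted p = 0.314 with an estimated correlation). The pals genes, some of which are known to respond to intracellular pathogens, rose in 15 of 27 cases and fell in 1 (median 0.20, camera adjusted p = 0.00048; adjusted p = 0.317 with an estimated correlation), 3 of them at least 2-fold. The medians of these families kept their sign under each scaling tried as well, and with the spike-in probes they lay between 0.37 (mrpl) and 0.56 (skr).

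Genes changed at least 2-fold by their fitted differences, also those with only a bound such as lys-9, often lay side by side. In the order of the tested genes, 30 adjacent pairs changed the same way, 14 higher and 16 lower, against 1.97 expected and at most 10 in 10000 permutations of the calls (p = 1e-04, the smallest they can give), which argues against chance placement. They form 25 runs, among them clec-127, clec-128, clec-131 and clec-132 (2.36 to 2.57 on the log2 scale), lips-11, lips-12 and lips-13 with col-40 (-1.55 to -1.03), and nlp-29, nlp-30 and nlp-31 (-1.52 to -1.17). For cross-hybridisation between similar genes, pairs with one symbol stem or with probes sharing a run of at least 15 bases were left out. Pairs of one clone name were left out only where neither gene has a symbol. This left 10 pairs, a number reached in 1 of the 10000 permutations. They still include pairs of one clone, such as lys-9 (C54C8.6) with C54C8.12 and sri-24 (C41G6.11) with C41G6.13. The count therefore cannot decide whether cross-hybridisation accounts for the whole excess, although no pair left had probes sharing such a run. Shared regulation of neighbouring genes and a difference in the genome between the flight and ground cultures may both produce such runs, and neither was tested.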
